A study of Mus musculus with 24 samples.

How the data were processed

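Per the labels, total RNA was enriched for mRNA and sequenced on an Illumina platform from CT26 cells in culture, from subcutaneous tumors at day 14 and from tumor cells purified from such tumors. Per the submitters' processing notes, FastQC, STAR and RSEM were used on the mm10 genome and DESeq2 for the comparisons, with versions not given in the sources used here. For each library the authors deposited an RSEM table with the expected count of each gene, TPM and FPKM. Per the file headers, the expected count is the estimated number of reads per gene, without scaling between libraries. The authors' TPM and FPKM values were used for no test. For each of the 3 comparisons the authors deposited a DESeq2 table with a signal (the mean of normalised counts), a log2 fold change with its standard error, a score (the Wald statistic), a p-value and an adjusted p-value, per the file headers. The header does not state the direction of that log2 fold change. In all 3 deposited tables Sun1 is positive, which makes it control over knockout.

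All 24 libraries were mapped to their groups from the labels, and 0 columns of values per sample were left unmapped. Expected counts were rounded to whole numbers. The comparisons, their tests, the gene lists, the rule for named genes and most alternatives were fixed before the data were examined. Fits used edgeR 4.0.16 in R 4.3.3 with TMM scaling, filterByExpr (minimum count 10, minimum total 15), robust dispersion estimates and the quasi-likelihood F test, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Each comparison was fitted on its own libraries. The control lines of purified cells form 1 arm in the knockout comparison and separate groups in the comparison of lines. Differences of the knockout effect between settings were tested as the interaction of setting and genotype. Standard errors were computed as the size of the log2 fold change over the square root of F. All tests are two-sided.

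The cultured fit has 1 residual degree of freedom and assumes that the lone knockout library varies as the control lines do. The labels do not say whether replicates are animals, pools or repeated libraries of the same RNA, so p-values measure only the spread between these samples. The chi-square per gene between libraries of the same group was at least 7.38, where repeated counting of 1 library would give about 1.

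Gene lists, 50 of them written by hand, were tested with camera of limma 3.58.1 at a preset correlation of 0.01 where at least 5 members were tested, adjusted over the lists of a comparison. Camera with an estimated correlation and the fry test were alternatives. Lists were called in 26 of 47 cases in tumors, 12 of 40 in purified cells and 13 of 38 in culture, and 1, 1 and 0 stayed called with an estimated correlation. Some genes belong to more than 1 list. The 13 mitochondrial genes were matched through their symbols without prefix.

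Genes were named by a fixed rule. It takes Sun1 and tested members of its list, then in each comparison the 10 largest changes per direction among called genes with a mean of at least 5 CPM in 1 arm and no overlap between arms, leaving out predicted models, pseudogenes and receptor segments. It then takes the 4 members with the smallest p of each called list and 2 of other lists described. Where no gene was called, the 5 genes with the smallest p are given as values. The text names a part of these genes. Genes carried from 1 comparison to another to compare them, and Nsd1 in cells, were chosen after their values were seen.

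Depth was 14140800 to 24651300 expected counts per library. Printed CPM values come from TMM scaling over all 24 libraries. For genes with 1 to 3 counts in an arm the ratio is given with a 95% exact binomial interval, and for genes with 0 counts a bound against a floor of 3 counts over the group. Both cover counting error only. The prior count of log2 CPM was 2.

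The steps were tested on simulated data, with 200 genes changed by known amounts among the real genes. For the tumor comparison 80.6%, 95.5% and 100% of genes changed 1.5-fold, 2-fold and 4-fold were recovered, with 10 unchanged genes called. For purified cells the shares were 26.9%, 83.6% and 95.5%, with 14 unchanged genes called. For culture they were 2.99%, 44.8% and 86.4%, with 47 unchanged genes called. Unchanged genes made up 4.65% of the 215 calls for tumors, 8.70% of 161 for purified cells and 33.3% of 141 for culture, so the last 2 exceed the 5% that the threshold allows. A list of 25 genes changed 1.5-fold was recovered by camera at the preset correlation in each comparison. The simulated genes varied independently of each other, so this does not test the effect of correlation within real lists. For the purified knockout comparison the control libraries were drawn around 1 common mean with independent spread. Recovery and false calls with distinct control lines in 1 arm were thus not tested.

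Alternatives were the size factors of DESeq2 (RLE), no filter on low counts, the DESeq2 1.42.0 test, a 2-fold minimum, all 24 libraries in 1 fit, the replicate number as a block, a block on the series of sample numbers in the deposited names, other control arms, and leaving out each library. A term for host cell content, the omission of X below 45 Mb and a joint fit of the 9 cell libraries were added after the data were seen.

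Coordinates of named genes come from RefSeq on GRCm38, the assembly that mm10 names. Positions along chromosome X come from GENCODE on GRCm38, where 26705 of 35976 symbols (74.2%) matched 1 gene and 58 that matched several were left out. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. The authors' tables served to check direction and overlap. Fold changes of the authors' tables and those computed here correlated across genes, which are not independent replicates, at 0.946 in tumors, 0.938 in purified cells and 0.914 in culture. At an adjusted p under 0.05 the deposited tables list 3058 genes higher and 2977 lower in knockout tumors and 618 and 676 in purified cells.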

Results

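RNA sequencing compared Sun1 knockout with control CT26 cells, a mouse colon carcinoma line that forms tumors in BALB/c mice. Sun1 encodes a protein of the inner nuclear membrane that ties the nuclear lamina to the cytoskeleton as part of the LINC complex. The 24 libraries came from 3 settings. Cultured cells gave 1 knockout library and 1 library from each of 2 control lines. Whole tumors collected 14 days after subcutaneous injection gave 7 knockout libraries and 8 control libraries, and the labels name control line 1 for all 8. Tumor cells purified from such tumors with a mouse tumor cell isolation kit gave 2 knockout libraries and 2 libraries from each control line. Total expected counts per library were 18832200 to 20716900 in culture, 14140800 to 24651300 in tumors and 17068400 to 22593600 in purified cells, over 35976 genes. The labels name 1 knockout line, so an effect of losing Sun1 and any other property of that line cannot be separated in any of the 3 settings.

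Sun1 lies on chromosome 5 from 139200564 to 139249839 (GRCm38), and its transcript was lower in each knockout library than in any control library of the same setting. In culture it measured 33.7 CPM in the knockout library and 116 CPM in the control lines (SD 9.03, n = 2). In tumors it measured 57.5 CPM (SD 5.19, n = 7) against 179 CPM (SD 8.60, n = 8), a log2 fold change of -1.63 ± 0.06 (SE; edgeR adjusted p = 4.56e-14). In purified cells it measured 53.2 CPM (range 50.9 to 55.5, n = 2) against 194 CPM in control line 1 (174 to 214, n = 2) and 166 CPM in control line 2 (165 to 167, n = 2), with a log2 fold change of -1.75 ± 0.14 (edgeR adjusted p = 0.000401). The cultured estimate was -1.79 ± 0.22 and missed the threshold (edgeR adjusted p = 0.150). Sun1 was thus 3.47-fold lower in culture, 3.09-fold lower in tumors and 3.37-fold lower in purified cells, and the tumor and purified effects differed by 0.13 (edgeR adjusted p = 0.548). Control line 2 did not differ from control line 1 in Sun1 (log2 fold change -0.22, edgeR adjusted p = 0.210). The authors' deposited tables give Sun1 as 1.51, 1.64 and 1.70 higher in control on the log2 scale in tumors, purified cells and culture.

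**Figure D1:**
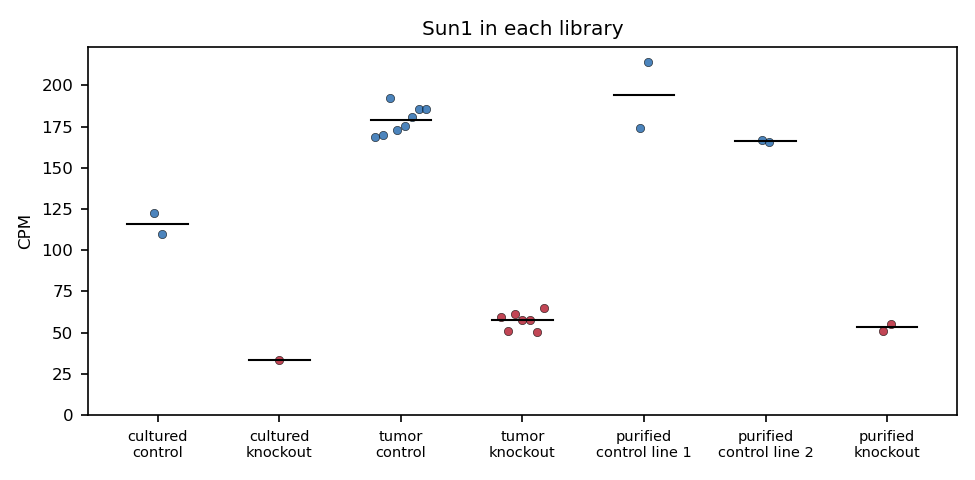
Sun1 level in CPM (y axis, linear) for each library, by setting and genotype (x axis); points are libraries and bars are group means. Knockout tumors lie between 50.5 and 64.8 CPM and control tumors between 169 and 192 CPM.

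In whole tumors the comparison asks how tumors from knockout cells, host cells included, differ from control tumors. Of 13752 genes tested, 2488 were higher and 2619 lower in knockout tumors at an edgeR adjusted p under 0.05, and 311 and 127 of them changed at least 2-fold. Among genes that rose most, Inmt, an enzyme that methylates indole amines, went from 1.53 to 17.6 CPM (log2 fold change 3.52 ± 0.54). Fstl1, a secreted glycoprotein of mesenchymal cells, rose from 30.8 CPM (SD 4.41, n = 8) to 99.4 CPM (SD 22.3, n = 7), by 1.70 ± 0.13 (edgeR adjusted p = 7.69e-08). The matrix protein Postn rose by 1.68, the matrix protein Dpt by 1.32, the ciliary transport gene Ift81 by 1.87 and cardiac troponin Tnnt2 by 1.72. Slamf9 (1.75), the chemokine receptor Xcr1 of cross-presenting dendritic cells (1.71) and the transcription factor Ikzf2 (1.62) rose as well, with Tcp11x2 (1.97) and Zc4h2 (1.68) on chromosome X. In each gene named in this paragraph apart from Dpt, which is a fibroblast marker named from its list, the rule for large changes required that the 7 knockout values lie wholly above the 8 control values.

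Among named genes Krt18, a keratin of simple epithelia, fell most in knockout tumors; it lies on chromosome 15 from 102028216 to 102032026. Its level went from 10.5 CPM (SD 1.63, n = 8) to 0.254 CPM (SD 0.177, n = 7), a log2 fold change of -5.37 ± 0.26 (edgeR adjusted p = 3.34e-12). The aldehyde dehydrogenase Aldh3a1 changed by -3.57, the ATP-gated channel P2rx3 by -2.95, the carnitine synthesis enzyme Tmlhe by -2.94 and the decoy receptor Tnfrsf26 by -2.62. Stra6, a retinol carrier receptor, changed by -2.57 and the matrix proteoglycan Prelp by -2.36. The parathyroid hormone-like hormone Pthlh changed by -1.80 and the adhesion receptor Ceacam1 by -1.77. Nsd1, a histone H3 lysine methyltransferase on chromosome 13 from 55209782 to 55318325, fell from 112 CPM (SD 12.3, n = 8) to 24.4 CPM (SD 2.96, n = 7), by -2.18 ± 0.09 (edgeR adjusted p = 1.6e-13). In the 9 libraries of cultured and purified cells, knockout and control alike, Nsd1 measured only 0.277 to 1.84 CPM, so tumors of both genotypes held far more of it than the cells (18.4 to 27.1 CPM in knockout tumors).

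**Figure D2:**
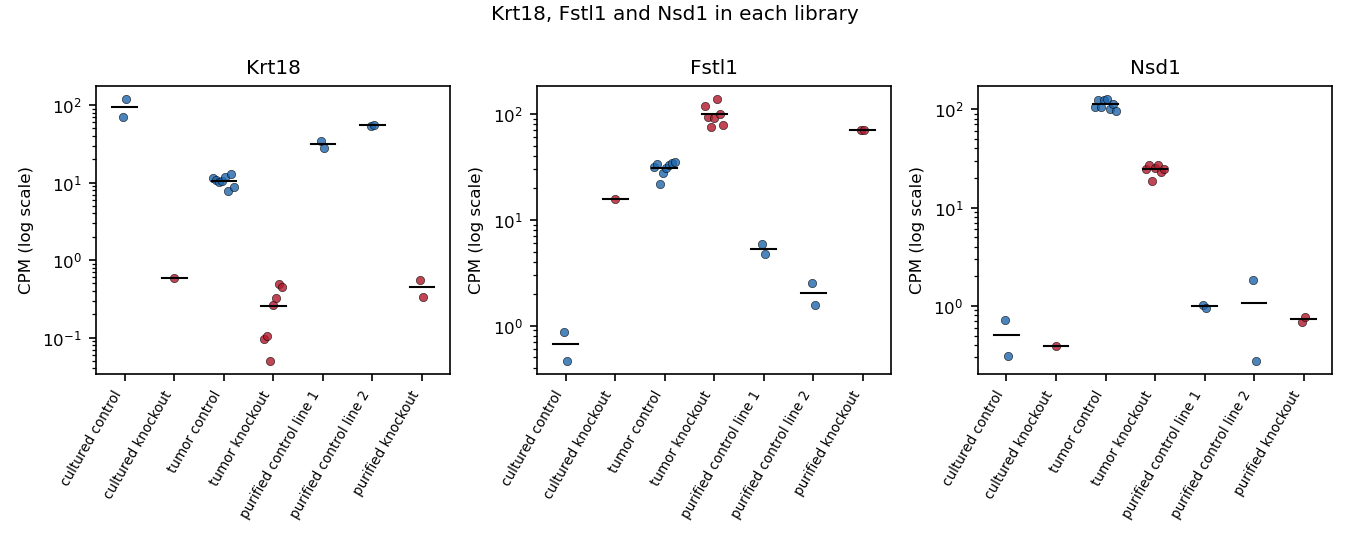
Level in CPM (y axis, log scale) of Krt18, Fstl1 and Nsd1 in each library, by setting and genotype (x axis); points are libraries and bars are group means. Krt18 averages 0.254 CPM in knockout tumors and 10.5 CPM in control tumors, and Nsd1 stays at or below 1.84 CPM in all 9 cell libraries.

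Other members of the nuclear envelope bridge also fell in knockout tumors. Sun2, the partner SUN-domain protein, went from 119 to 81.0 CPM (log2 fold change -0.55 ± 0.07, edgeR adjusted p = 9.68e-06). Syne3, which encodes nesprin-3, changed by -0.63 ± 0.09 and Syne2, which encodes nesprin-2, by -0.52 ± 0.10 (edgeR adjusted p = 1.92e-05 and 0.00102). Of 19 tested members of the list of LINC complex and nuclear lamina genes, 9 fell and 0 rose, also 9 when adjusted over the list alone (limma camera adjusted p = 0.000297, median -0.11). Sun1, the gene knocked out, is among the members that fell, and the list was not tested without it. That list was not called with an estimated correlation (limma camera adjusted p = 0.112). In purified cells Sun2 again fell (-0.80 ± 0.11, edgeR adjusted p = 0.00367), while Syne3 (-0.40) and Syne2 (-0.25) were not called.

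Transcripts of lymphocytes were higher in knockout tumors. Of 20 tested T cell markers 15 rose and 0 fell, or 16 adjusted over the list alone, with a median log2 fold change of 0.63 (limma camera adjusted p = 1.38e-07; adjusted p = 0.289 with an estimated correlation). The T cell receptor chain Cd3g rose from 11.1 CPM (SD 2.59, n = 8) to 30.1 CPM (SD 6.07, n = 7), by 1.45 ± 0.14 (edgeR adjusted p = 7.77e-07), Cd3d by 1.21 and the coreceptor Cd8a by 1.24 ± 0.20. Among 13 natural killer cell markers 7 rose, or 8 adjusted over the list alone, with Klrd1 at 1.45 and a median of 0.81 (limma camera adjusted p = 0.000151; 0.412 with an estimated correlation). Of 18 cytotoxic effector genes 8 rose by either adjustment, over all genes or adjusted over the list alone, among them Eomes (1.31) and interferon gamma, Ifng (1.08 ± 0.22), with a median of 0.81 (limma camera adjusted p = 0.000501; 0.412 with an estimated correlation). Of 14 checkpoint and exhaustion genes 9 rose and 1 fell, or 10 and 1 adjusted over the list alone, with Pdcd1, which encodes PD-1, at 1.00 (limma camera adjusted p = 0.000222; 0.112 with an estimated correlation).

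Markers of several other cell types were higher as well. Of 8 mast cell and eosinophil markers 7 rose, or 8 adjusted over the list alone, with the IgE receptor chain Fcer1a at 1.00 and the chymase Cma1 at 0.91 (limma camera adjusted p = 0.000195; 0.412 with an estimated correlation). Of 18 endothelial markers 7 rose by either adjustment, over all genes or adjusted over the list alone, with Pecam1 at 0.53 and Eng at 0.55 (limma camera adjusted p = 0.00162; 0.484 with an estimated correlation). Of 9 MHC class II genes 3 rose, or 4 adjusted over the list alone, with H2-Ab1 at 1.09 (limma camera adjusted p = 0.0209; 0.585 with an estimated correlation). Of 15 dendritic cell markers 6 rose, or 7 adjusted over the list alone (limma camera adjusted p = 0.0311; 0.412 with an estimated correlation and 0.0520 with the block on sample numbers). Skeletal muscle markers rose in 9 of 13 members, or 10 adjusted over the list alone, with the myosin Myh4 at 4.14 and Ckm at 2.93 (limma camera adjusted p = 0.0109; 0.585 with an estimated correlation), and these markers were also higher in the cultured knockout library. Macrophage markers were not called as a list (limma camera adjusted p = 0.0622), with 5 of 20 higher, among them Aif1 (1.32), and 2 lower, or 6 and 2 adjusted over the list alone. They were called when knockout replicate 6 or control replicate 2, 5 or 7 was left out (limma camera adjusted p = 0.0104, 0.0412, 0.0245 and 0.0363). Fibroblast markers split, with 8 of 20 higher and 5 lower, or 9 and 6 adjusted over the list alone, Dpt at 1.32 and Dcn at -1.02 (limma camera adjusted p = 0.196). Neutrophil markers included 3 of 9 that fell, also 3 adjusted over the list alone, with Mmp8 at -1.80 (limma camera adjusted p = 0.365).

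A term for host cell content, the mean log2 CPM of Ptprc (CD45) and Pecam1 per tumor, was added after the values were seen, and it left 39 genes higher and 157 lower in knockout tumors. Genotype explained 76.9% of the variance of that term, which averaged 6.59 (SD 0.156, n = 7) in knockout and 6.02 (SD 0.176, n = 8) in control tumors without overlap. Host content and genotype therefore could hardly be separated in these tumors. With the term, type I interferon-stimulated genes (median 0.52, limma camera adjusted p = 3.33e-13), cholesterol synthesis genes (-0.47), glycolysis genes (-0.28), cytotoxic effector genes (1.09) and natural killer cell markers (0.44) remained called in the same direction, as did the checkpoint and mast cell lists (limma camera adjusted p = 0.0466 and 0.0202). T cell markers (median 0.34), MHC class I genes (0.086) and nucleic acid sensing genes (0.13) lost their call (limma camera adjusted p = 0.0519, 0.471 and 0.0799). Interferon gamma-induced genes (0.11), TGF-beta targets (0.097) and unfolded protein and integrated stress response genes (-0.032) lost it as well (limma camera adjusted p = 0.983, 0.147 and 0.475). The dendritic, endothelial and skeletal muscle lists changed the sign of their median. MHC class II genes, macrophage markers and monocyte markers became called as lower (-0.56, -0.68 and -0.47, limma camera adjusted p = 0.0403, 0.000207 and 0.0194). The term is itself made of host cell transcripts, and Pecam1 is a member of the endothelial list. Lower values of host cell lists with the term are thus partly built in.

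Interferon-stimulated genes were higher in knockout tumors. Of 30 type I interferon-stimulated genes 28 rose and 0 fell, or 29 adjusted over the list alone, with a median of 0.44 (limma camera adjusted p = 1.26e-09; 0.412 with an estimated correlation). Oasl1 rose by 0.58 ± 0.08, the master regulator of type I interferon Irf7 by 0.67 ± 0.10 and the signal transducer Stat2 by 0.51 ± 0.09. Of 21 genes of MHC class I antigen presentation 11 rose, or 12 adjusted over the list alone, with H2-Q7 at 0.97 (limma camera adjusted p = 0.000501; 0.412 with an estimated correlation). Of 21 genes that sense nucleic acids in the cytosol 9 rose and 2 fell, or 10 and 2 adjusted over the list alone (limma camera adjusted p = 0.0265; 0.412 with an estimated correlation). Of 25 interferon gamma-induced genes 11 rose and 3 fell, or 15 and 4 adjusted over the list alone (limma camera adjusted p = 0.0280; 0.667 with an estimated correlation). That last call was lost without knockout replicate 6 or control replicate 1, 3 or 5 (limma camera adjusted p = 0.0522, 0.0693, 0.0504 and 0.0911).

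Metabolic groups moved in both directions in tumors. All 13 mitochondrially encoded genes rose, also 13 adjusted over the list alone, with CYTB at 0.48 and ND3 at 0.82 (limma camera adjusted p = 1.67e-07; 0.412 with an estimated correlation), and together they took 4.76% of counts in knockout (SD 0.343, n = 7) and 3.54% in control tumors (SD 0.501, n = 8). Of 28 nuclear oxidative phosphorylation genes 14 rose and 1 fell by either adjustment, over all genes or adjusted over the list alone, with Ndufa4 at 0.65 (limma camera adjusted p = 0.00364; 0.412 with an estimated correlation). Of 30 ribosomal protein genes 16 rose, or 17 adjusted over the list alone, with Rps14 at 0.44 (limma camera adjusted p = 0.000495; 0.585 with an estimated correlation). Glycolysis genes fell in 14 of 18 members and rose in 1, the same counts adjusted over the list alone, with the lactate exporter Slc16a3 at -1.11 ± 0.11 and pyruvate kinase Pkm at -0.43 (limma camera adjusted p = 5.36e-06; 0.412 with an estimated correlation). Hypoxia-induced genes fell in 11 of 22 members and rose in 3, the same counts adjusted over the list alone, with Ndrg1 at -1.10 (limma camera adjusted p = 0.0174; 0.610 with an estimated correlation). Cholesterol synthesis genes fell in 14 of 21 members, or 16 adjusted over the list alone, and rose in 0, with the sterol regulator Srebf2 at -0.81 ± 0.08 and squalene epoxidase Sqle at -0.68 (limma camera adjusted p = 5.36e-06; 0.412 with an estimated correlation).

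Stress, signalling and identity genes of the tumors changed as well. Of 24 unfolded protein and integrated stress response genes 7 fell by either adjustment, over all genes or adjusted over the list alone, with the cystine carrier Slc7a11 at -1.02 and Asns at -0.57 (limma camera adjusted p = 0.00680; 0.536 with an estimated correlation). Of 19 NF-kappaB targets 11 fell and 0 rose, or 11 and 1 adjusted over the list alone, with Nfkb2 at -0.54 (limma camera adjusted p = 0.00574; 0.289 with an estimated correlation). Of 19 genes of the mesenchymal transition 10 fell and 1 rose, or 11 and 1 adjusted over the list alone, with vimentin, Vim, at -0.48 (limma camera adjusted p = 0.00134; 0.248 with an estimated correlation). Of 6 epithelial genes 3 fell by either adjustment, over all genes or adjusted over the list alone, Krt18 most, and this list alone among the 26 called lists stayed called with an estimated correlation (limma camera adjusted p = 0.000195 and 0.0417). It was not called without the filter on low counts (limma camera adjusted p = 0.116). The epithelial list had a median of -0.27, 2 of its 6 members were higher by any amount, and it was not tested without Krt18. Among 23 p53 targets 8 rose and 2 fell, or 9 and 3 adjusted over the list alone, with Ccng1 at 0.66 (limma camera adjusted p = 0.0311; 0.412 with an estimated correlation), and the call was lost without knockout replicate 3 or control replicate 5 (0.0642 and 0.0575). Among 19 TGF-beta targets 7 rose and 1 fell, the same counts adjusted over the list alone, with Id3 at 1.25 and Ctgf at 1.05 (limma camera adjusted p = 0.0395; 0.412 with an estimated correlation). The TGF-beta call was lost without knockout replicate 1 or 5 or control replicate 2, 4, 5 or 8 (limma camera adjusted p = 0.0604, 0.0621, 0.0522, 0.0556, 0.0812 and 0.0588), and with the block on sample numbers (0.0581). Genes of the G2 and M phases were not called (median -0.02, limma camera adjusted p = 0.706), nor were S phase genes (limma camera adjusted p = 0.260).

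In purified tumor cells the comparison, with both control lines in the control arm, asks which differences lie in the tumor cells themselves. Of 12476 genes tested, 282 were higher and 286 lower in knockout cells at an edgeR adjusted p under 0.05, and 117 in each direction changed at least 2-fold. Fstl1, on chromosome 16 from 37777055 to 37836516, rose to 70.4 CPM from 5.30 CPM in control line 1 and 2.05 CPM in control line 2 (n = 2 each), by 4.29 ± 0.41 (edgeR adjusted p = 0.00229). The tissue inhibitor of metalloproteinases Timp3 rose by 3.52 ± 0.29, Dpt by 3.05 ± 0.26 and the growth factor Bmp2 by 2.42 ± 0.22, to a mean of 151 CPM (edgeR adjusted p = 0.000449, 0.000541 and 0.00109). The calcium channel subunit Cacng7 rose by 4.06, the interferon-induced Ifi44l by 2.35, Sdsl by 2.31, the chemokine Ccl5 by 2.23 and the matricellular protein Nov by 2.23. The myosin Myh4 had the largest value (5.73 ± 1.11, edgeR adjusted p = 0.0350), but the libraries of the knockout measured 1.01 and 16.1 CPM and its call was lost without knockout replicate 2 (edgeR adjusted p = 0.462), control line 1 replicate 1 or 2 (0.106 and 0.103) or control line 2 replicate 1 or 2 (0.0911 and 0.0517).

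Some genes were close to silent in purified knockout cells. Krt18 averaged 0.445 CPM in knockout cells and 31.2 and 54.9 CPM in control lines 1 and 2 (log2 fold change -6.57 ± 0.48, edgeR adjusted p = 0.000449). The scaffold kinase gene Cask, on chromosome X from 13517080 to 13846783, had 3 counts in the knockout libraries together and 1464 in the controls, a ratio of 272 (95% interval 93.1 to 1323). Aldh5a1, which degrades GABA, had 3 against 585 counts, a ratio of 109 (37.1 to 530). Tmlhe changed by -6.94 ± 0.38, the protein kinase gene Prkx by -6.48 ± 0.45 and the palmitoyltransferase gene Zdhhc15 by -5.85 ± 0.64 (edgeR adjusted p = 0.000116, 0.000172 and 0.00161). Gas7 (-2.84), the Wnt ligand Wnt10b (-2.45), Rcan2 (-2.32) and Zfp600 (-2.21) fell by smaller amounts. In whole tumors Cask still measured 4.60 CPM in knockout against 15.2 CPM in control, and Prkx 11.4 against 15.9 CPM.

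Interferon-stimulated genes had the highest median of the called lists in purified knockout cells. Of 30 type I interferon-stimulated genes 28 rose and 0 fell, or 30 adjusted over the list alone, with a median of 1.49 (limma camera adjusted p = 3.42e-103). This list also stayed called with an estimated correlation (limma camera adjusted p = 0.0446). Ifit3 rose from 40.3 to 157 CPM (1.97 ± 0.12), Ifit3b by 2.06 ± 0.12, Stat2 by 1.67 and the tethering factor Bst2 by 1.62 (edgeR adjusted p = 0.000116 for Ifit3). Of 20 cytosolic nucleic acid sensing genes 8 rose and 1 fell, or 12 and 1 adjusted over the list alone, with the RNA sensors Ifih1 at 1.26 and Dhx58 at 1.44 (limma camera adjusted p = 2.25e-09; 0.0707 with an estimated correlation). Of 25 interferon gamma-induced genes 7 rose, or 13 adjusted over the list alone, with Cxcl10 at 1.58 and Gbp6 at 1.24 (limma camera adjusted p = 2.25e-09; 0.797 with an estimated correlation). Of 21 MHC class I genes 5 rose, or 12 adjusted over the list alone, with their activator Nlrc5 at 1.27 and H2-D1 at 0.58 (limma camera adjusted p = 2.48e-09; 0.746 with an estimated correlation). Without knockout replicate 2 the calls of Nlrc5, Gbp6, Cxcl10 and H2-D1 were lost (edgeR adjusted p = 0.0594, 0.0759, 0.256 and 0.277). H2-D1 was also not called without knockout replicate 1, control line 1 replicate 1 or 2, or control line 2 replicate 2 (edgeR adjusted p = 0.259, 0.0577, 0.0592 and 0.0708).

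Cholesterol synthesis genes fell in purified knockout cells. Of 20 members 12 fell and 0 rose, or 18 adjusted over the list alone, with a median of -1.05 (limma camera adjusted p = 1.66e-18; 0.421 with an estimated correlation). Acat2 fell by 1.47 and Srebf2 by 1.17 on the log2 scale, and neither stayed called without knockout replicate 2 (edgeR adjusted p = 0.0543 and 0.144). Macrophage markers, left over at low level, were lower in 2 of 16 members and higher in 1, or 5 and 1 adjusted over the list alone, with Lyz2 at -1.91 and Msr1 at -2.76 (limma camera adjusted p = 0.0135; 0.882 with an estimated correlation), and the list was not called without control line 2 replicate 1 (0.0790), with separate line means (0.0592) or against control line 1 or 2 alone (0.0706 and 0.0807). Lyz2 and Msr1 each lost their call when either knockout library was left out (edgeR adjusted p = 0.240 and 0.325 for Lyz2, 0.259 and 0.337 for Msr1). Lyz2 also lost it without control line 1 replicate 2 (edgeR adjusted p = 0.0661), and Msr1 without control line 1 replicate 1 or 2 or control line 2 replicate 1 (edgeR adjusted p = 0.0622, 0.0714 and 0.0680). Skeletal muscle markers rose in 3 of 10 members, or 4 adjusted over the list alone (median 1.01, limma camera adjusted p = 0.00901; 0.797 with an estimated correlation), but without knockout replicate 2 their median was -0.12 (limma camera adjusted p = 0.511), and they were not called with separate line means (0.0592) or against control line 2 alone (0.264). Of 30 ribosomal protein genes 0 were called by edgeR over all genes and 0 adjusted over the list alone, 27 were lower by any amount, and the list was called as lower (median -0.24, limma camera adjusted p = 0.00658; 0.909 with an estimated correlation), though not without knockout replicate 2 (0.178). Dendritic cell markers were called as higher (median 0.16 over 5 members, limma camera adjusted p = 0.00359; 0.403 with an estimated correlation), and their 1 called member, also 1 adjusted over the list alone, was the interferon-stimulated Bst2. They were not called without the filter on low counts (limma camera adjusted p = 0.473) or against control line 2 alone (0.0894). Immediate early genes were higher in 1 of 19 members, or 4 adjusted over the list alone (median 0.31, limma camera adjusted p = 0.00358; 0.797 with an estimated correlation and 0.120 against control line 2 alone). Epithelial genes were lower in 1 of 7 members, Krt18, also 1 adjusted over the list alone (limma camera adjusted p = 0.0135; 0.403 with an estimated correlation and 0.208 without the filter on low counts). S phase genes were called as lower (median -0.18, limma camera adjusted p = 0.0497; 0.909 with an estimated correlation), with 1 of 26 members higher over all genes and 1 adjusted over the list alone. That call was lost without either knockout library or either library of control line 2 (limma camera adjusted p = 0.0921, 0.0580, 0.0785 and 0.194), and with RLE scaling, the replicate block or control line 1 alone (0.0539, 0.0585 and 0.515). Glycolysis genes (limma camera adjusted p = 0.182) and mitochondrially encoded genes (0.964) were not called in purified cells. Against control line 1 alone, the line named for the control tumors, mitochondrially encoded genes were called as higher (median 0.28, limma camera adjusted p = 0.0156).

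The purified calls rested on both knockout libraries. Without knockout replicate 1 edgeR called 56 genes higher and 52 lower, and without knockout replicate 2 it called 41 and 31. Sun2, Cacng7, Sdsl, Nov and Rcan2 lost their call in both cases (edgeR adjusted p without replicate 1 of 0.0518, 0.0634, 0.0771, 0.103 and 0.0771, and without replicate 2 of 0.111, 0.105, 0.117, 0.175 and 0.167). Wnt10b and Zfp600 lost it without replicate 1 alone (edgeR adjusted p = 0.0906 and 0.0734). Ifit3 and Ifit3b, the H2 genes, Tcp11x2 and Zfp600 have close relatives in the genome, so the split of shared reads among them leaves their single values uncertain.

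**Figure D3:**
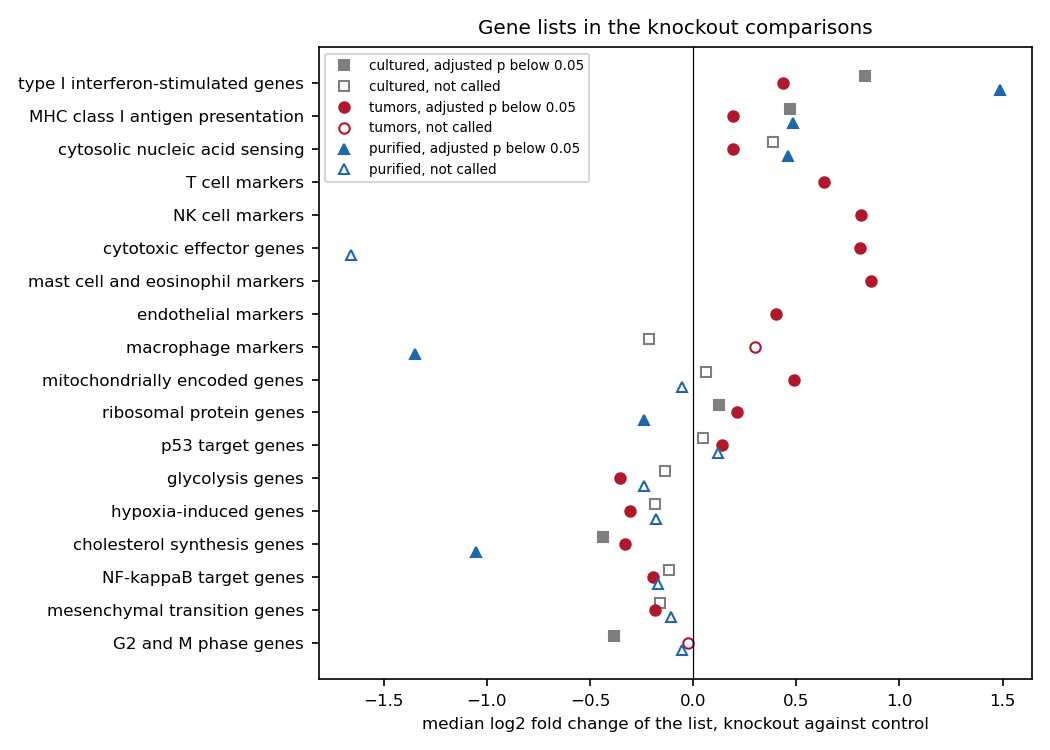
Median log2 fold change of gene lists (x axis, knockout against control) for each list (y axis) in cultured cells, tumors and purified tumor cells; filled points have a limma camera adjusted p under 0.05. Type I interferon-stimulated genes stand at 0.44 in tumors and 1.49 in purified cells, and cholesterol synthesis genes at -0.33 and -1.05.

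Between tumors and purified cells, which share no library, 12209 genes were tested in both. Of these, 148 rose in both settings where independent lists would share 45.02, and 207 fell in both where independent lists would share 59.9. In the opposite direction, 14 genes that rose and 7 that fell in purified cells were called the other way in tumors. Fstl1 and Dpt rose and Krt18, Tmlhe, Sun2 and Srebf2 fell in both. The difference of the knockout effects between the settings was called for 1249 genes, 550 with a larger value in tumors and 699 with a smaller one. That count dropped to 455 without purified knockout replicate 1 and to 254 without replicate 2. The tumor effect is against control line 1 alone, while the purified effect is against both control lines. With only control line 1 in the purified set 1517 genes were called. Interferon-stimulated genes moved less in tumors than in purified cells, by a median of -1.07 with 26 of 30 genes called, or 28 adjusted over the list alone (limma camera adjusted p = 2.35e-36; 0.108 with an estimated correlation). Cask (6.27), Prkx (6.01) and Zdhhc15 (4.22) were lower by far less in tumors, while Ceacam1 (-2.69), Timp3 (-3.39) and Cacng7 (-2.95) had a smaller value there.

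In culture the single knockout library was set against both control lines, and the spread between those lines stood in for that of replicates. Of 12175 genes edgeR called 0, with 659 at an unadjusted p under 0.05 where chance would give 609, and a smallest adjusted p of 0.0734. DESeq2 called 17 higher and 32 lower, and the authors' deposited table lists 16 and 31. The genes with the smallest p repeated those of purified cells. Bmp2 measured 51.3 against 5.43 CPM (3.23 ± 0.28) and Fstl1 15.6 against 0.671 CPM (4.52 ± 0.50). Krt18 measured 0.592 against 94.4 CPM (-7.31 ± 0.58) and Prkx differed by -6.26 ± 0.51. Tmlhe had 2 counts against 658, a ratio of 177 (95% interval 48.9 to 1469). Lists were called in culture on the preset correlation, 7 higher and 6 lower, while none was with an estimated one (limma camera adjusted p of at least 0.925). With 1 knockout library these calls rest on the members of a list in place of replicates, so they cannot separate the knockout from the variation of a single library. In that library interferon-stimulated genes stood higher by a median of 0.83 over 29 members, MHC class I genes by 0.47 over 21 and, with Psmb8 at 2.18, interferon gamma-induced genes by 0.45 over 20 (limma camera adjusted p = 2.78e-07, 1.16e-08 and 0.000335). The interferon-stimulated median was 0.20 against control line 1 and 2.36 against control line 2. Matrix proteases stood higher by 0.20 over 15 members, with Mmp13 at 3.33 (limma camera adjusted p = 1.59e-05). Skeletal muscle markers stood higher by 2.26 over 10 members, 1 of them called adjusted over the list alone (limma camera adjusted p = 5.98e-08), with 35 counts of Myh4 against 2. Without the filter on low counts the interferon gamma and matrix protease lists were not called (limma camera adjusted p = 0.116 and 0.0679). Genes of the G2 and M phases (-0.38, 26 of 26 lower), S phase genes (-0.39, 24 of 26 lower), DNA repair genes (-0.33) and cholesterol synthesis genes (-0.44, 20 of 20 lower) stood lower in the single knockout library (limma camera adjusted p = 1.88e-07, 6.31e-07, 0.000232 and 1.24e-05). Adjusted over the list alone, 0 interferon-stimulated, cholesterol synthesis, DNA repair, S phase or G2 and M phase genes, 2 MHC class I genes, 1 interferon gamma-induced gene and 4 matrix protease genes were called. Against purified cells, 0 genes had a different knockout effect by edgeR, with 553 at an unadjusted p under 0.05 where chance would give 660, and DESeq2 called 8. In simulated data this comparison recovered 1.49% of 1.5-fold and 13.4% of 2-fold changes, so the 0 says little. For the same difference 6 lists had a larger value in culture and 5 a smaller one, among them cholesterol synthesis genes (0.56) and interferon-stimulated genes (-0.64; limma camera adjusted p = 9.61e-07 and 0.00706), and none was called with an estimated correlation (at least 0.726).

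The control lines gave a yardstick for differences between lines that both carry Sun1. In purified cells 840 genes were higher and 1124 lower in control line 2 than in control line 1 by edgeR, and that count dropped from 1964 to 791 or 853 without control line 1 replicate 1 or 2. Fits that also kept the control lines apart called 1038 genes higher and 1262 lower in the knockout against control line 1, and 1369 and 1307 against control line 2. The ion channel Cnga1 had 0 counts in line 1 and 489 in line 2, at least 142-fold higher against a floor of 3 counts over the group. The cancer-testis antigen Magea8 had 0 against 217 counts, at least 63.0-fold higher. The stromelysin Mmp3 was higher by 4.41 ± 0.16, the nonclassical class I gene H2-T23 by 4.40 ± 0.23 and Il13ra1 by 4.97 ± 0.35 (edgeR adjusted p = 5.73e-09, 7.52e-07 and 6.2e-05). The matrix genes Lum (-5.72) and Eln (-3.56) and the synaptic gene Syt1 (-7.36) were lower. Of 22 collagen and matrix genes 10 were lower, or 13 lower and 1 higher adjusted over the list alone (median -0.58, limma camera adjusted p = 1.55e-08; 0.484 with an estimated correlation). All 13 mitochondrially encoded genes were called higher adjusted over the list alone and 10 over all genes (median 0.58, limma camera adjusted p = 1.55e-08; 0.646 with an estimated correlation). In all, 12 lists were called higher and 3 lower in control line 2, none of them with an estimated correlation (limma camera adjusted p of at least 0.484) or by fry. Of 25 interferon gamma-induced genes 7 were higher and 1 lower, or 12 and 1 adjusted over the list alone, with a median of 0.51 (limma camera adjusted p = 1.02e-05; 0.750 with an estimated correlation). Of 21 MHC class I genes 6 were higher, or 9 higher and 1 lower adjusted over the list alone, with a median of 0.27 (limma camera adjusted p = 2.28e-06; 0.750 with an estimated correlation). The knockout medians of these 2 lists in purified cells were 0.75 and 0.48. The type I interferon-stimulated list was not called between the control lines (median -0.11, limma camera adjusted p = 0.190).

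Purification was assessed in libraries labelled control line 1, by setting 2 purified libraries against 8 tumors. These differences include any between the cells that formed those tumors and the purified cells. Transcripts of several host cell types, though not of all, were lower in purified cells by similar medians. All 20 T cell markers were lower (median -6.16), as were 19 of 20 macrophage markers (-6.13), 8 of 8 mast cell and eosinophil markers (-6.30) and 17 of 20 endothelial markers (-5.71). Adjusted over the list alone these counts were 20, 20, 8 and 17 (limma camera adjusted p = 2.83e-15, 1.14e-18, 1.14e-18 and 4.34e-13; 0.0857, 0.0876, 0.0349 and 0.0636 with an estimated correlation). Fibroblast markers were not called as a list (median 0.28, with 8 of 21 higher and 9 lower, limma camera adjusted p = 0.557). Neither were skeletal muscle markers (1 of 14 higher and 2 lower, limma camera adjusted p = 0.778). Pecam1 went from 34.9 to 0.511 CPM (-6.12 ± 0.22), Cd68 from 51.8 to 0.727 CPM and Cd3g from 11.1 to 0.170 CPM. S phase genes were higher in purified cells in 17 of 26 members, or 18 adjusted over the list alone, and cholesterol synthesis genes in 17 of 21, also 17 adjusted over the list alone (limma camera adjusted p = 4.73e-05 and 4.08e-05; 0.406 and 0.478 with an estimated correlation). Krt18 was higher by 1.54 ± 0.15, at 31.2 against 10.5 CPM.

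Along chromosome X, genes below 45 Mb (GRCm38) were lower in the knockout in all 3 settings, a limit chosen after the values were seen. In purified cells 88 of 92 tested genes there had a log2 fold change below 0, 63 were called lower and 0 higher by edgeR, and the median was -1.001. In tumors 85 of 101 lay below 0, with 70 called lower, 5 called higher and a median of -0.52. In culture 84 of 89 lay below 0 with a median of -0.88 and no gene was called there by edgeR, as in the rest of that comparison. The rest of X had medians of 0.02 in culture, 0.00 in purified cells and 0.07 in tumors, and between the control lines the stretch had a median of 0.02. Cask lies in this stretch, while Prkx and Zdhhc15 do not. Smaller shifts ran along other chromosomes. On chromosome 15 from 80 to 90 Mb, where Srebf2 lies, medians were -0.37 in culture, -0.35 in purified cells and -0.27 in tumors, with 53 of 94 genes called lower by edgeR in tumors. On chromosome 7 medians were 0.47 in culture and 0.38 in purified cells from 20 to 30 Mb, and 0.45 and 0.44 from 30 to 40 Mb, while tumors had -0.07 and 0.01. Between the control lines chromosome 13 from 60 to 70 Mb had a median of -0.49. With the stretch of X left out, 282 genes were higher and 223 lower in purified knockout cells.

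**Figure D4:**
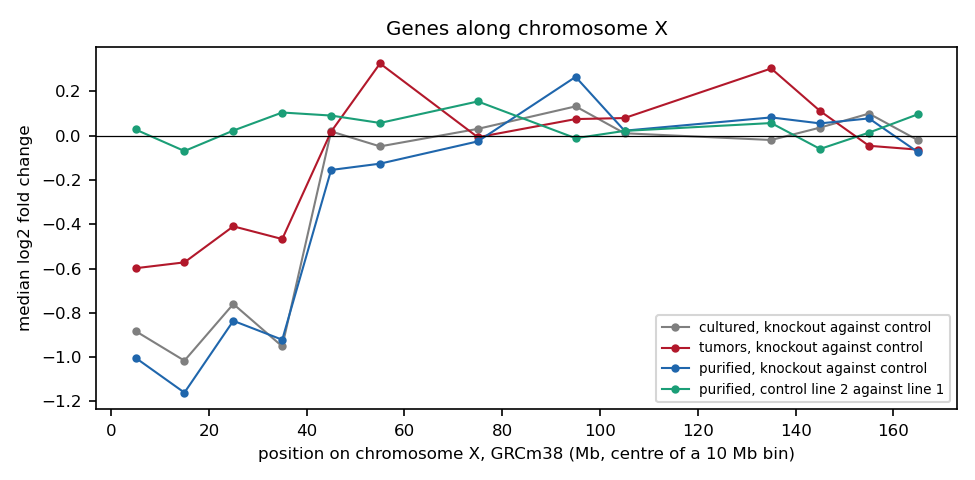
Median log2 fold change (y axis) of genes in bins of 10 Mb along chromosome X (x axis, Mb, GRCm38) for knockout against control in culture, tumors and purified cells and for control line 2 against control line 1. Below 45 Mb the knockout comparisons have medians of -0.88, -0.52 and -1.001, and the control lines 0.02.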

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

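The tests of explanations for the interferon pattern were chosen only after the result was seen, while the splits of the tumors into other groups were planned.

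Single tumors stood far from the others of their group in 16 of 178 checks, where chance would give 8.9. Knockout replicate 6 had the highest Ift81 (159 CPM, next 97.9) and Ccng1 (195 CPM) and the lowest Tmlhe (0.372 CPM), Slc16a3 (22.8 CPM) and Vim (3654 CPM). The same tumor had the lowest mean log2 CPM of NF-kappaB targets (5.09), hypoxia-induced genes (5.19) and glycolysis genes (7.94). Knockout replicate 1 had the highest Myh4 (17.7 CPM, next 3.47) and Ckm (16.3 CPM) and the lowest mean log2 CPM of cytotoxic effector genes (3.05, next 4.25). Knockout replicate 5 stood apart in T cell markers (mean log2 CPM 3.21). Control replicate 2 had the highest Irf7 (236 CPM), Cd3g (16.5 CPM) and mean log2 CPM of checkpoint and exhaustion genes (3.30), and control replicate 5 the highest Sqle (183 CPM).

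Values here are the knockout effect in tumors minus that in purified cells. Among genes that the text took from the rule in both comparisons, 4 differed. These were Fstl1 (-2.59), Tmlhe (3.99), Stat2 (-1.16) and Dpt (-1.73), with edgeR adjusted p of 0.000223, 3.51e-05, 7.22e-05 and 0.00102. Genes carried from 1 comparison to the other, such as Cask and Prkx, are not in that count. Lists with a smaller value in tumors were type I interferon-stimulated genes (-1.07), interferon gamma-induced genes (-0.51), MHC class I genes (-0.29), cytosolic nucleic acid sensing (-0.20), the unfolded protein and integrated stress response (-0.21), immediate early genes (-0.33) and heat shock genes (-0.19). Their limma camera adjusted p were 2.35e-36, 9.27e-05, 0.000393, 0.000389, 0.0474, 0.00626 and 0.00755. Lists with a larger value in tumors were cytotoxic effector genes (2.58), macrophage markers (1.69), mast cell and eosinophil markers (2.15), S phase genes (0.29), oxidative phosphorylation genes (0.20), mitochondrially encoded genes (0.63), ribosomal protein genes (0.40) and cholesterol synthesis genes (0.61). Their limma camera adjusted p were 0.0198, 2.98e-05, 0.00451, 0.000608, 0.000608, 9.27e-05, 2.06e-09 and 1.88e-07. With an estimated correlation none of these lists was called, at limma camera adjusted p from 0.108 to 0.758. Few members of the cytotoxic, macrophage and mast cell lists were called by edgeR. Of 18, 20 and 9 members, 0, 2 and 0 had a larger value in tumors and 1, 1 and 0 a smaller one. In control line 1 these lists were lower in purified cells than in tumors by medians of -6.00, -6.13 and -6.30. Their large differences thus rest on low counts in purified cells. The tumor effect is against control line 1 alone and the purified effect against both control lines. Differences between the control lines therefore enter these values. Mitochondrially encoded genes had a purified median of 0.28 against control line 1 alone (limma camera adjusted p = 0.0156), beside 0.49 in tumors.

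Interferon-stimulated genes were higher in purified knockout cells by a median of 1.49. Immune cells left after purification were argued against. To supply the excess, a median of 86.5% (quartiles 60.7% and 110%) of the interferon gene level of whole knockout tumors would have to be carried over with them. Immune markers of at least 20 CPM in those tumors kept a median of 0.420% (quartiles 0.249% and 1.26%, 53 genes) of their level. A low level in 1 control line only was argued against as well, since the median was 1.37 against control line 1 and 1.63 against control line 2, with 29 of 30 genes called each time. A difference already present in culture stays open, with medians of 0.20 against control line 1 and 2.36 against control line 2 from single libraries. A consequence of losing Sun1 and a chance property of this knockout line may each explain the pattern, and no test here separates them. Other causes, host cells without immune markers among them, were not covered by these tests.

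In tumors, 1 of 100 splits of the 15 libraries into 7 and 8, the real one, reached the real total of 5107 calls. That total thus depends on the labels. Other splits mix the genotypes, which adds their difference to the spread and lowers the counts. The splits cannot test for chance properties of the lines. The highest other split gave 1084 calls and kept 6 of the 7 knockout tumors together.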

How the results depend on the processing

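Joint fits of 9 libraries, the omission of X below 45 Mb and the term for host cell content were chosen after the data were seen, and the other tests were planned.

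Pooled over the alternatives, most calls in tumors kept their direction and their side of the threshold. Over the alternatives, 3334 of 3498 values of called genes and 521 of 572 values of called lists did, and 12 genes and 5 lists among them changed direction. In purified cells 720 of 866 and 130 of 168 did and none of those changed direction, and in culture 22 of 52 values of called lists did. Most tumor alternatives left out 1 library and so share most samples, which raises the pooled share. With an estimated correlation only 1 of 26 called tumor lists stayed called. With the term for host cell content only 24 of 159 called named genes did, while 123 lost their call and 12 changed direction. The fry test, which does not compare a list with other genes, called 30 lists in tumors, 5 in purified cells and 0 in culture, where limma camera called 26, 12 and 13. The direction of a list is that of its camera test, and these counts cover only what the main analysis called. Of lists called only afterwards, 2 changed direction in tumors and 1 in purified cells. Medians of purified lists did cross 0, the skeletal muscle list to -0.12 and the dendritic list to -0.010 without knockout replicate 2, the dendritic list to -1.01 without the filter and the epithelial list to 0.30 against control line 2 alone. The tumor epithelial median became 0.32 without the filter. Counts of tumor calls stayed within 1.5 times under RLE scaling (2551 and 2547), DESeq2 (2804 and 2719), the block on sample numbers (2571 and 2766) and each omitted library (2166 to 2519 higher and 2322 to 2645 lower), and fell to 311 and 127 at a 2-fold minimum, which is stricter by construction.

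With the term for host cell content 39 genes were higher and 157 lower in knockout tumors. Medians that changed sign were MHC class II (-0.56), dendritic (-0.22), endothelial (-0.14), macrophage (-0.68), monocyte (-0.47) and skeletal muscle markers (-0.74), and for interferon gamma-induced genes (median 0.11) the test did. Genes that changed sign were Atp2a1 (-0.71), Cadm1 (-0.091), Cd79b (-0.087), Ckm (-1.43), Ctss (-0.51), Des (-1.33), Esam (-0.014), Fcgr1 (-0.24), H2-Ab1 (-0.19), H2-Eb1 (-0.39), Myh4 (-0.74) and Tnni2 (-0.61). Genotype explained 76.9% of the variance of that term, so a lost call there does not separate host content from genotype. The term is made of host cell transcripts, so lower values of host cell lists with it are partly built in.

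In culture edgeR called 42 genes higher and 53 lower without the filter on low counts, DESeq2 called 17 and 32, the fit of all 24 libraries 154 and 189 and the joint fit of 9 libraries 47 and 84. Both larger fits borrow the spread of other libraries by construction. For the rest the cause was not tested. Without the filter the epithelial list (median 0.072) changed its direction in culture. Leaving out a control library there leaves no residual degrees of freedom, so only log2 fold changes were computed.

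In purified cells the counts higher and lower were 454 and 454 without the filter, 553 and 586 with DESeq2, 117 and 117 at a 2-fold minimum and 1122 and 1074 with all 24 libraries. With separate line means they were 1305 and 1265, against control line 1 alone 1038 and 1262, and against control line 2 alone 1369 and 1307. Separate lines take the difference between control lines out of the spread by construction. For the others the cause was not tested. Leaving out 1 library gave 41 to 262 higher and 31 to 278 lower, with fewer samples. Mitochondrially encoded genes were higher against control line 1 alone (median 0.28).

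The replicate number as a block gave 156 and 147 calls in purified cells, 2432 and 2533 in tumors and 1823 between control lines. The numbers did not pair the tumors. In tumors deviations of the same number correlated at -0.17 to 0.32 over 7 pairs, and 0 of 7 correlated best with their own number. In purified cells the correlations were -0.0040, 0.13 and -0.13 for the 3 pairs of groups. Knockout and control line 2 libraries correlated best with their own number in 2 of 2 cases. With 2 libraries per group these values cannot settle whether the numbers pair samples.

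Genes that differ between control lines numbered 412 at a 2-fold minimum and 791 to 2215 with 1 library left out. Those with another knockout effect in tumors than in purified cells numbered 1915 with DESeq2 and 254 to 1353 with 1 library left out, and for culture 7 without the filter, 8 with DESeq2 and 0 to 1 with 1 library left out. Purified against whole tumors gave 2797 at a 2-fold minimum and 5546 to 8000 with 1 library left out.

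Depth limits genes near the floor. At 14140800 to 24651300 counts a gene at 0 counts is bounded only by 3 counts.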

Other observations

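Tests of the stretch of chromosome X and of the identity of the control tumors were all chosen only after the results were seen.

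Genes of chromosome X below 45 Mb were lower in the knockout line, by a median of -0.88 in culture, -1.001 in purified cells and -0.52 in tumors. Fewer copies of this stretch in the knockout line are a candidate explanation, as its median in culture was -0.88 while that of the rest of X was 0.02. The stretch was found in the same values, and genomic DNA was not analysed here. A lower expression of the stretch with the same number of copies stays open. A stretch that varies between lines whatever their Sun1 status may be the cause too. Its median was 0.023 between the control lines, but other stretches differed between them, such as chromosome 13 from 60 to 70 Mb (median -0.49).

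The tumors labelled control line 1 differed from the cells of control line 1 in Nsd1, at 95.6 to 126 CPM in 8 tumors against 0.953 and 1.03 CPM in purified cells. Knockout tumors also held more Nsd1 than knockout cells, at 18.4 to 27.1 CPM against 0.394 to 0.774 CPM. A gap to the cells was thus seen in both genotypes, but it was larger in control tumors. Host cells that rose with Ptprc and Pecam1 in knockout tumors were argued against as the whole source of the higher level in control tumors. Nsd1 itself changed by -2.18 in knockout tumors. A host cell type richer in control tumors stays open. In knockout tumors 5 of 20 fibroblast markers were called lower and 8 higher, and 3 of 9 neutrophil markers lower and 0 higher. Tumors grown from other cells than control line 1 stay open, and so does expression in tumor cells that is lost on purification. For genes that mark a line, the purified difference of the knockout from control line 1 was set beside that between tumors. Genes that mark control line 1 kept 19.8% of it, and 25 of 33 went the same way (exact binomial p = 0.00455). Genes that mark the knockout line kept 51.5% (32 of 34). Genes that mark control line 2 kept 9.38% (25 of 42, exact binomial p = 0.280). Their purified difference of the knockout from control line 1 was small (median size 0.54), so this value cannot test a likeness of the tumors to control line 2. The binomial tests count genes, which are not independent replicates, so their p-values measure no spread between tumors or lines. If the control tumors came from other cells, part of the tumor differences may reflect those cells, and the limits used here were set after the values were seen.

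Aldh5a1 had 0 counts in the cultured knockout library and 254 in the control lines. Skeletal muscle transcripts were seen in the cultured knockout library as well, where Myh4 had 35 counts against 2 in the control libraries, a ratio of 32.4 (95% interval 8.33 to 278). Acta1 had 14 against 1, a ratio of 25.95 (3.95 to 1097), and Ckm 15 against 2, a ratio of 13.9 (3.23 to 125).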
